A study of Mus musculus with 6 samples.

How the data were processed

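The series holds 6 samples, of which 4 single-cell gene expression libraries were analysed, 1 library per group. The 2 NILER V(D)J samples were not analysed here. Each deposited table lists genes by cells in natural log units, as ln of 1 plus 10000 times the cell's UMIs of a gene over the cell's UMIs of all listed genes. The submitters' processing notes name Cell Ranger and Seurat and the genome build GRCm38, without versions. The labels give the single-cell 5′ gene expression kit version 1.1 for all 4 libraries, yet their barcodes differ by model: those that begin with AAACCC or AAACCT were all AAACCC in YUMMER (7 and 13) and all AAACCT in NILER (31 and 31). The plan had assumed counts. Each value was therefore inverted and divided by the smallest positive value of its cell, which gave whole UMIs within 0.01 for 100% of values in all 4 libraries. Cells held at least 199 genes as deposited. The deposited tables listed 18280 and 18015 genes for YUMMER control and sh3 and 15714 and 16105 genes for NILER shCTR and shITCH, and a gene missing from 1 table of a pair was taken as 0.

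Cells with at least 200 genes and at most 15% mitochondrial UMIs were kept. Doublets were scored with Scrublet in scanpy 1.11.5 at an expected 0.8% per 1000 cells, with the automatic threshold, or the top scores where that called under 0.5%. This left 6992 and 6307 YUMMER cells and 8051 and 9296 NILER cells. Median mitochondrial shares of the deposited cells were 3.24% and 6.27% in YUMMER and 1.88% and 2.44% in NILER. In YUMMER 12.6% and 21.6% of cells were above 15%.

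The 2 libraries of a model were clustered jointly, with no batch correction. UMIs were scaled to 10000 per cell and log transformed, 2000 variable genes were scaled with a cap of 10, and 30 components and 15 neighbours fed Leiden clustering at resolution 1. Receptor segment, mitochondrial and ribosomal protein genes did not enter the variable genes. A cluster took the name of the cell class with the most of its fixed markers among the cluster's top 50 genes, with at least 3 markers, and 20 classes had markers. Unnamed clusters of at least 100 cells were split once more at resolution 0.5. Clusters with puroR of at least 30 CPM and Xist below 20 CPM were called vector-bearing. Both thresholds were set after the data had been seen, because the melanocytic markers planned for tumour cells were near absent. Clusters whose median UMIs were below the library median divided by 3 were named only with a marker among their 10 leading genes.

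Expression of a class is its summed UMIs per 1000000 UMIs of the class. Intervals on CPM are exact Poisson intervals, those on ratios are exact conditional binomial intervals, and those on shares are exact Clopper-Pearson intervals, all at 95%. With 1 library per group no test between groups was made. A count of 0 was compared through a floor of 3 counts. Counts of genes at least 2-fold higher or lower describe size among genes with at least 100 summed UMIs in classes of at least 50 cells per library. For 29 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 20 summed UMIs. Its interval comes from order statistics of the members, and its percentile from 10000 random lists matched over 25 expression bins. Subset shares count T-like cells with at least 1 UMI of a marker, and were repeated with each cell thinned to 1000 UMIs.

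Genes named in the text follow a rule fixed before the data were examined. It takes, per class, the genes with the largest ratio by the interval bound nearest 1 among those with at least 100 summed UMIs, leaving out mitochondrial, ribosomal protein, sex-linked, haemoglobin, receptor segment and predicted genes. Up to 8 each way are named for the largest class of a model and up to 4 for others. It adds up to 4 members of each list described and 16 genes always read: Itch, Cd274, Pdcd1, Cd8a, Cd4, Foxp3, Gzmb, Ifng, Prf1, Mki67, Dusp6, B2m, Cxcl9, Cxcl10, Arg1 and Xist. Genes outside the rule were chosen after their values were seen, among them leading genes of clusters. Coordinates come from GENCODE M21.

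The steps from counts to ratios were tested on simulated data, Poisson counts drawn around the means of both libraries of a class, with 200 genes changed per class by 1.5-fold, 2-fold or 4-fold. The step held 11167 genes in YUMMER vector-bearing cells, 4458 in YUMMER T-like cells, 9217 in NILER T-like cells and 3908 in NILER macrophage-like cells. In all 4 classes 100% of genes changed 4-fold came out at least 2-fold. Of genes changed 2-fold 54.5%, 50.0%, 45.3% and 51.9% did so in these classes, and of genes changed 1.5-fold 0%, 6.25%, 0% and 1.64%. The 95% intervals held the true fold for 90.7% to 100% of changed genes and for 95.4%, 96.2%, 95.3% and 95.9% of unchanged genes. The simulated counts vary by counting error alone, which is what the intervals assume. This coverage therefore says nothing about spread between libraries. All 20 genes named by size in each class had changed as drawn, and a list of 20 genes shifted by 0.5 on the log2 scale lay at percentile 100 in each class. Clustering and naming of cells were not simulated. Of 200 unshifted lists 4%, 4%, 6.5% and 3% fell outside the central 95% of random lists. Their genes were drawn independently, so this does not cover lists whose genes vary together.

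The 17 alternatives fixed in advance vary the mitochondrial and gene filters, doublet removal, clustering and naming, the scaling (trimmed mean of M values, with 30% and 5% trimmed, and CPM without mitochondrial and ribosomal protein genes), the depth per cell and the minimum of UMIs. The other 5 were chosen after seeing the data. A check for lymph node tissue in the YUMMER control sample is not reported here. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. The seed was 0.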

Results

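The data are single-cell RNA counts from mouse melanomas treated with trametinib, a drug that blocks the MAPK pathway kinase MEK. The series title concerns PD-L1, the ligand of the T cell checkpoint receptor PD-1, and ITCH, an E3 ubiquitin ligase that marks proteins for degradation. In each of 2 melanoma models a library from tumours with a hairpin against Itch was compared with a library from tumours with a control hairpin or no named hairpin. YUMMER1.7 is a melanoma line with mutant Braf, and its libraries came from dissociated tumours at day 14. NILER1-4 is a line with mutant Nras, and its libraries came from tumour cells sorted for CD45, a surface protein of blood cells, at day 5. Per the labels, the 5′ end of each transcript was counted with unique molecular identifiers (UMIs).

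The YUMMER control library held 8151 cells and 75456866 UMIs, and the YUMMER sh3 library held 8174 cells and 68800303 UMIs. The NILER shCTR library held 9194 cells and 40127644 UMIs, and the NILER shITCH library held 10747 cells and 53204882 UMIs. Median UMIs per cell were 5128 and 6205 in YUMMER control and sh3, and 2934 and 3673 in NILER shCTR and shITCH. Each group is 1 library, so there are no replicates. Intervals on CPM, ratios and shares cover counting error only, and those on list medians cover the spread between member genes. Expression is given as UMIs per 1000000 UMIs of the class (CPM), the control library first, and each ratio is hairpin library over control library with its 95% exact interval. Shares carry 95% Clopper-Pearson intervals. Cell classes were named from marker transcripts, and the name "T-like" or "B-like" says no more than that.

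Itch is the gene the hairpins target. It lies on chromosome 2 from 155133509 to 155226855 on the plus strand of GRCm38 (ENSMUSG00000027598). In YUMMER cells carrying puroR, a puromycin resistance gene of the kind used in hairpin vectors, Itch was lower in the sh3 library, at 24.9 CPM (23.7 to 26.2; 1546 UMIs) and 16.9 CPM (15.8 to 18.0; 976 UMIs). The ratio was 0.677 (0.624 to 0.734). All 10 clusters of these vector-bearing cells had less Itch in the sh3 library, with ratios from 0.503 to 0.866. Over all YUMMER cells the ratio was 0.713 (0.662 to 0.767), from 26.3 CPM (1871 UMIs) and 18.8 CPM (1184 UMIs). In the 7 other YUMMER classes compared the interval of the Itch ratio spanned 1. puroR was 220 and 82.9 CPM in vector-bearing cells, and some was found in other classes, as in T-like (9.63 and 7.79 CPM), mast or basophil-like (39.5 and 17.7) and macrophage-like cells (81.6 and 5.03). Itch was 40.9 and 55.5 CPM in T-like cells (ratio 1.36, 0.975 to 1.87), 68.9 and 61.1 CPM in NK-like cells (0.887, 0.513 to 1.59), and 28.8 and 34.5 CPM in endothelial-like cells (1.2, 0.713 to 1.99).

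In the CD45-sorted NILER cells Itch was not lower in the shITCH library. Over all cells it was 32.3 CPM (30.4 to 34.2; 1117 UMIs) in shCTR and 36.6 CPM (34.9 to 38.4; 1663 UMIs) in shITCH, a ratio of 1.14 (1.05 to 1.23). T-like cells held 28.3 and 32.2 CPM (1.14, 1.01 to 1.28), NK-like cells 36.2 and 42.4 CPM (1.17, 1.01 to 1.36), and macrophage-like cells 32.8 and 35.8 CPM (1.09, 0.669 to 1.87). The labels do not say which cells received the hairpin. In the sorted cells the NILER pair therefore compares blood cells from tumours of the 2 arms, not cells with less Itch.

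**Figure D1:**
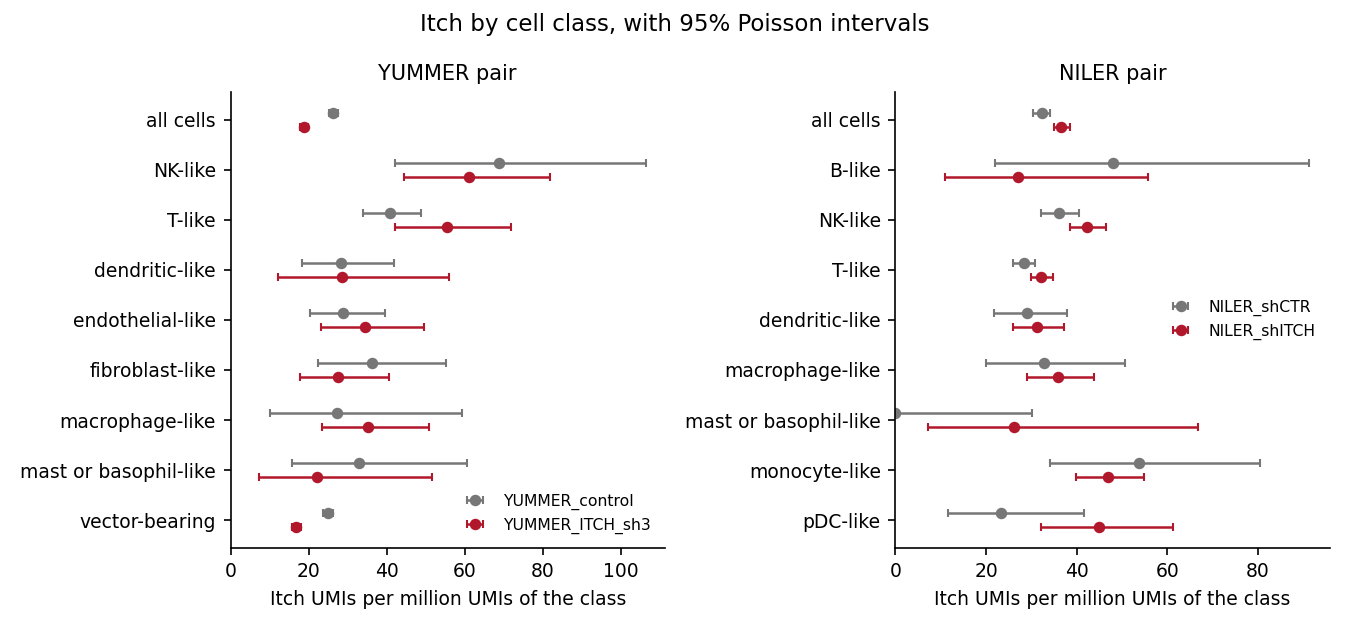
Itch CPM of each cell class (horizontal axis) in the 4 libraries, points being the measured value and bars 95% Poisson intervals. Vector-bearing YUMMER cells held 24.9 CPM in the control and 16.9 CPM in the sh3 library, while all NILER cells held 32.3 and 36.6 CPM.

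The YUMMER libraries address how the cell content of a treated tumour differs when Itch is targeted. The sh3 library held lower shares of B-like, T-like and monocyte-like cells and higher shares of macrophage-like, NK-like, fibroblast-like and vector-bearing cells. B-like cells were 5.42% (4.90 to 5.98; 379 cells) of kept cells in the control and 0.0317% (0.00384 to 0.115; 2 cells) in the sh3 library, 171-fold lower (47.0 to 1417). That fold rests on 2 cells and on the clusters. Without clusters or a mitochondrial limit, cells with at least 2 B cell marker UMIs were 5.19% (423 cells) and 0.22% (18 cells), a smaller difference. T-like cells were 19.1% (18.2 to 20.03; 1335 cells) and 7.10% (6.48 to 7.77; 448 cells), 2.69-fold lower (2.41 to 3.00). Macrophage-like cells were 1.56% (109 cells) and 7.28% (459 cells), a ratio of 4.67 (3.78 to 5.81), and monocyte-like cells were 3.82% (267 cells) and 0.539% (34 cells), 7.08-fold lower (4.95 to 10.4). Macrophage-like and monocyte-like cells combined were 5.38% and 7.82%, a ratio of 1.45 (1.27 to 1.67). The size of these myeloid differences depends on the processing: over the alternatives the log2 ratio ran from 0.41 to 4.43 for macrophage-like cells, from -3.01 to -0.98 for monocyte-like cells and from 0.07 to 1.21 for both combined.

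NK-like cells, lymphocytes that kill without an antigen receptor, were 1.36% (1.1 to 1.66) and 3.69% (3.24 to 4.19) of YUMMER cells, a ratio of 2.72 (2.13 to 3.49). Dendritic-like cells were 2.13% and 1.11%, fibroblast-like cells 1.87% and 3.74%, endothelial-like cells 4.62% and 3.82%, and mast or basophil-like cells 2.79% and 2.65%. Vector-bearing cells were 52.8% (3691 cells) and 67.8% (4275 cells), a ratio of 1.28 (1.23 to 1.34). Among named immune cells alone, T-like cells were still lower in the sh3 library, at 52.4% and 31.0%, and macrophage-like cells higher, at 4.28% and 31.8%. The NK-like direction turned at a clustering resolution of 0.5. T-like and NK-like cells together were 20.5% and 10.8%, a ratio of 0.528 (0.481 to 0.579). The naming rule for shallow clusters left out 1 cluster with puroR at 116 CPM, which makes up the unnamed 4.16% of control cells and 1.65% of sh3 cells.

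**Figure D2:**
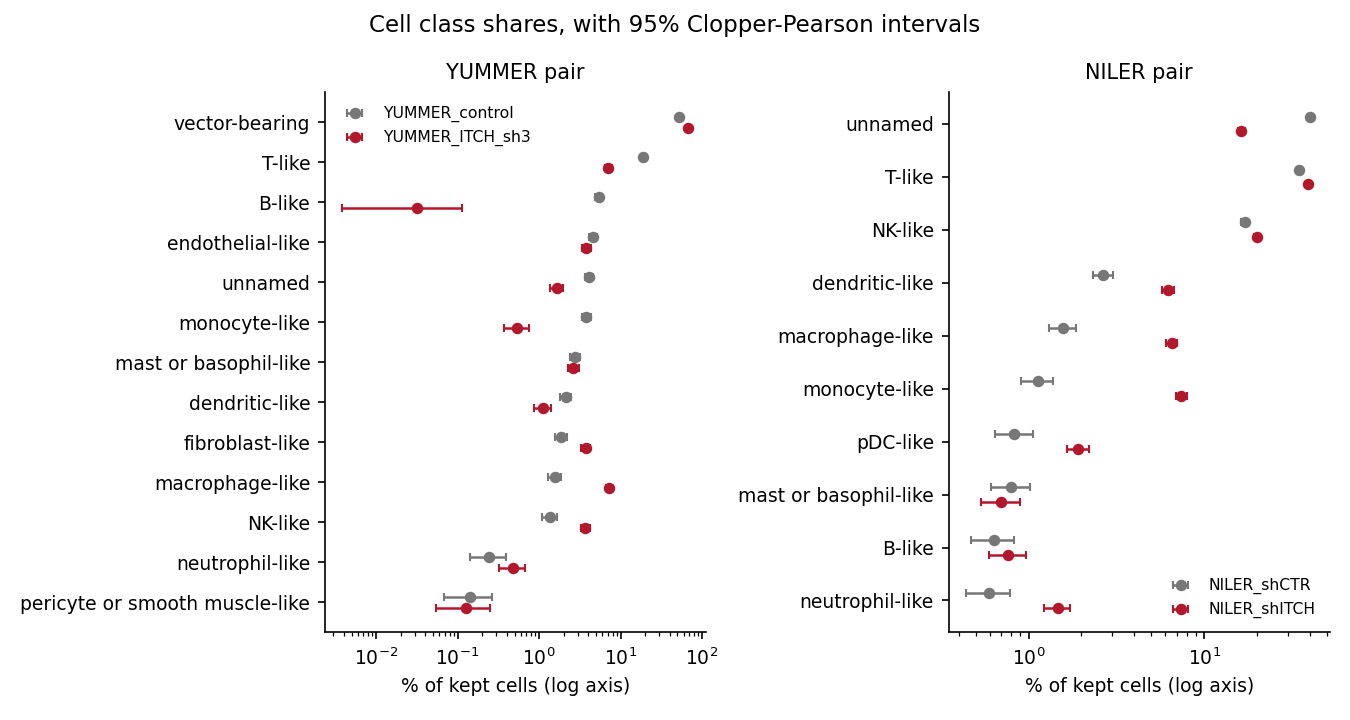
Share of kept cells in each class (horizontal log axis, %) in the YUMMER pair and the NILER pair, with points for the measured share and bars for 95% Clopper-Pearson intervals. B-like cells were 5.42% of the YUMMER control and 0.0317% of the sh3 library, and NILER monocyte-like cells were 1.13% of shCTR and 7.40% of shITCH.

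The vector-bearing YUMMER cells show what the tumour compartment expresses when Itch is targeted under trametinib. Interferon-response and MHC class I transcripts were lower in the sh3 library, and transcripts of the extracellular matrix, of hypoxia and of the T cell receptor and activation list, which holds the Nr4a receptors, were higher. Of 26 measured genes of the interferon gamma response 20 were lower, with a median log2 ratio of -0.33 (-0.67 to -0.06). That median lay at percentile 0.01 of random lists of like abundance. Such lists do not allow for genes that vary together, so the percentile describes these 2 libraries and is not a test. Ifi47, an interferon-induced GTPase, was 104 and 58.6 CPM (0.565, 0.541 to 0.589), Tgtp2 6.24 and 2.82 CPM, and the T cell attractant Cxcl10 248 and 156 CPM (0.629, 0.613 to 0.645). Cxcl9, another attractant of T cells, went the other way at 4.13 and 11.4 CPM (2.77, 2.39 to 3.21). Of 27 type I interferon genes 19 were lower (median -0.33, -0.60 to 0.02), among them Ifit3 at 132 and 54.4 CPM and Mx1 at 9.81 and 5.36 CPM, while Oas3 was higher at 3.13 and 5.63 CPM.

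MHC class I presents peptides to CD8 T cells, and 15 of its 18 measured genes were lower in the sh3 library (median -0.25, -0.52 to -0.07). H2-D1 was 1843 and 1124 CPM, H2-Q7 23.8 and 10.1 CPM, H2-Q4 123 and 82.3 CPM, and B2m 3175 and 2158 CPM (0.680, 0.675 to 0.684). Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095, plus strand), was slightly higher at 8.35 and 10.1 CPM (1.21, 1.07 to 1.36; 518 and 582 UMIs). Among 9 genes of the PD-1 and PD-L1 axis 3 were higher and 6 lower (median -0.05, -0.14 to 0.24). Cops5, a deubiquitinase that stabilises PD-L1, was lower at 103 and 71.2 CPM, and Cmtm6, which protects PD-L1 from degradation, was higher at 10.5 and 12.4 CPM. Of the 9 measured genes of ITCH and its partners 6 were lower. The related ligase Wwp2 was 69.2 and 44.2 CPM, and Smurf1 and Smurf2 were higher with ratios of 1.37 and 1.29.

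Extracellular matrix genes were higher in the sh3 vector-bearing cells for 18 of 22 members (median 0.46, 0.04 to 1.28), with Col6a2 at 193 and 748 CPM, Thbs2 at 50.2 and 143 CPM and Tnc at 6.66 and 17.7 CPM. Timp3, an inhibitor of matrix proteases, was lower at 286 and 91.1 CPM. Hypoxia and glycolysis genes were higher for 20 of 22 members (median 0.34, 0.03 to 0.64), with the carbonic anhydrase Car9 at 0.435 and 2.11 CPM and Pdk1 at 10.1 and 24.6 CPM. The T cell receptor and activation list was higher for 12 of 15 members (median 0.60, 0.06 to 1.00), with Nr4a1 at 77.5 and 227 CPM and Nr4a2 at 36.0 and 128 CPM. The dissociation stress list, which shares some of these genes, was higher for 15 of 21 members, with a median interval that spans 0 (0.10, -0.04 to 0.53). MAPK output genes were mixed, with 13 of 21 higher (median 0.21, -0.13 to 0.59): the feedback phosphatase Dusp6 was 46.7 and 51.6 CPM (1.1, 1.05 to 1.16), Epha4 5.14 and 9.64 CPM, and the feedback inhibitor Spry1 40.3 and 14.7 CPM. Dusp6 turned slightly lower in the sh3 library when only cells of at most 5% mitochondrial UMIs were kept. Of 24 cell cycle genes 10 were higher and 14 lower (median -0.03, -0.14 to 0.10), and Mki67 at 45.4 and 48.6 CPM turned lower when cells were thinned to 1000 UMIs.

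Among single genes chosen by rule in these vector-bearing cells, the largest ratios above 1 belonged to Retnla (0.129 and 2.51 CPM), Atp8a1 (0.177 and 2.35), the complement component C3 (7.06 and 48.7; ratio 6.90, 6.23 to 7.64), the nuclear receptor Nr4a3 (8.65 and 56.6; 6.55, 5.97 to 7.18), Gpc3 (0.242 and 2.37), Sirpa (1.05 and 7.5), Fabp4 (4.79 and 29.5) and Stra6 (2.59 and 16.4). The largest ratios below 1 belonged to Lyzl4 (128 and 0 UMIs; at least 39.8-fold lower), the protease inhibitor Slpi (2.95 and 0.0691 CPM), Akr1cl (2.61 and 0.0691), Jchain (3.05 and 0.121), Smoc2 (5.01 and 0.294), P2ry14 (2.64 and 0.121), Gria3 (5.72 and 0.363) and the chemokine Cxcl12 (19.1 and 1.57; 12.2-fold lower, 9.82 to 15.2). Of 11162 genes with at least 100 summed UMIs, 157 were at least 2-fold higher and 183 at least 2-fold lower. Retnla was also higher in macrophage-like cells (667 and 5284 CPM; 109 and 459 cells), and all 4 measured haemoglobin genes were higher (median 5.38). Jchain is a plasma cell marker, and B-like cells numbered 379 in the control and 2 in sh3. RNA carried over from other cells is therefore not excluded for Retnla and Jchain. All 13 mitochondrially encoded transcripts were higher in the sh3 library (median 0.68, 0.50 to 0.81), as happens where cell quality differs, and the medians of the YUMMER classes ran from 0.40 to 1.11. The mix of clusters differed too. Cluster 2, with Gbp9 and Ifi47 among its leading genes, held 26.3% and 5.08% of the vector-bearing cells. Cluster 4, led by Ifit3, Ifit1 and Rsad2, held 11.5% and 5.73%. Cluster 5, led by Eln, Mfap4, Mmp2 and Thbs2, held 11.5% and 23.1%, and cluster 22, led by Acta2, Ogn and Aspn, held 4.61% and 16.9%.

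**Figure D3:**
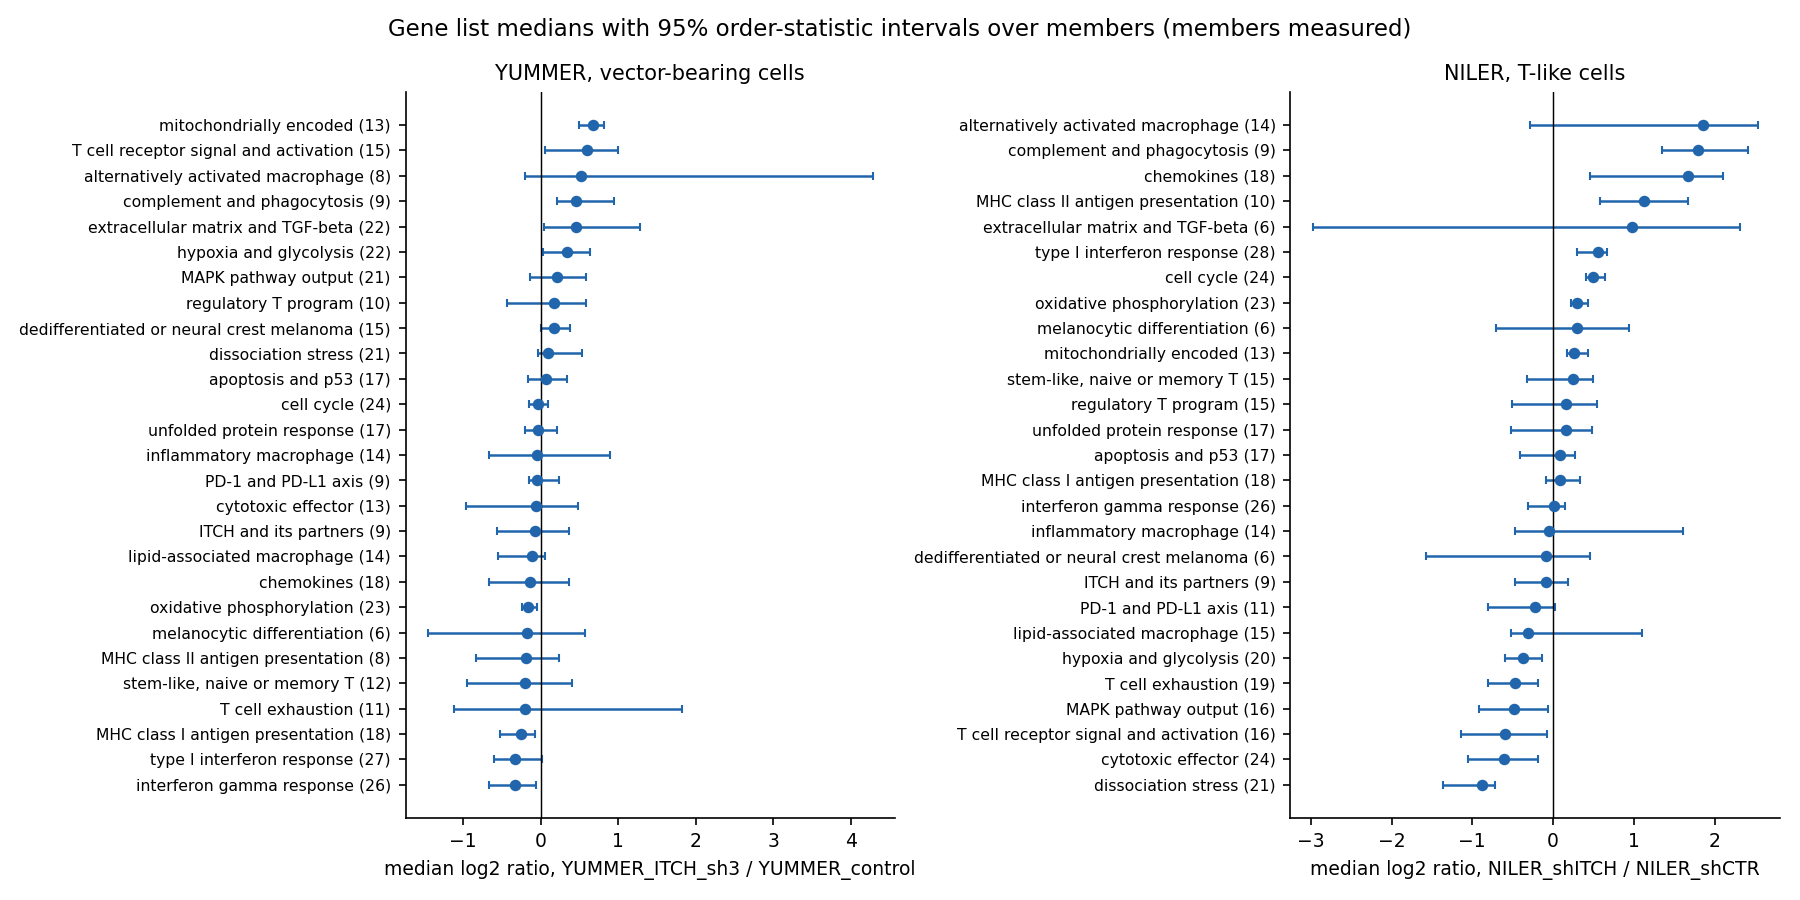
Median log2 ratio of each gene list (horizontal axis; hairpin library over control library) in YUMMER vector-bearing cells and NILER T-like cells, with bars for 95% order-statistic intervals and the number of measured members in brackets. The interferon gamma response median was -0.33 in the YUMMER cells and 0.02 in the NILER cells, and the T cell receptor list was 0.60 and -0.59.

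In YUMMER T-like cells the sh3 library held less of the effector-memory granzyme Gzmk and of the checkpoint receptors Pdcd1 and Lag3, more Gzma and more of the regulatory T cell program. Gzmk was 178 and 5.84 CPM (536 and 6 UMIs; 0.0328, 0.0120 to 0.0719) and Gzma 69.1 and 757 CPM (11, 9.39 to 12.8), a direction that turned where each cell was named by its highest mean marker. Pdcd1, which encodes PD-1, was 130 and 44.8 CPM (0.344, 0.248 to 0.468), Lag3 51.1 and 16.6 CPM, and Rgs16 616 and 230 CPM. Of 18 exhaustion genes 11 were lower (median -0.31, -0.85 to 0.66). Of 15 genes of the regulatory T program 12 were higher (median 0.98, 0.13 to 1.55), among them Il1rl1 at 53.8 and 230 CPM, Il2ra at 72.4 and 214 CPM, Ikzf2 at 186 and 516 CPM and Foxp3 at 21.6 and 55.5 CPM (2.57, 1.77 to 3.73). T-like cells with a Foxp3 UMI were 2.92% (2.09 to 3.97) and 8.26% (5.88 to 11.2), where 0 of 95 and 0 of 233 NK-like cells had one. Background was higher in myeloid classes, at 2.75% (0.571 to 7.83) and 3.05% (1.68 to 5.06) of macrophage-like and 0.375% and 5.88% of monocyte-like cells, so the control T-like share is near background. Thinned to 1000 UMIs per cell the shares were 0.896% and 5.46%.

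Scaling by trimmed means, in place of plain UMI totals, shifted every log2 ratio of the YUMMER T-like cells by 0.21, so values between 0 and 0.21 turn negative under it. The lower bounds of the regulatory T list and of both interferon lists lie below that shift, and their medians above it: 19 of 22 interferon gamma genes (median 0.50, 0.17 to 0.97) and 23 of 27 type I interferon genes (median 0.45, 0.14 to 0.95) were higher, with Rsad2 at 44.2 and 91.5 CPM, Slfn5 at 17.9 and 49.7 CPM and Cxcl10 at 43.5 and 161 CPM. Cytotoxic genes were mixed, with 13 of 22 higher (median 0.29, -0.67 to 1.16). Gzmb was 318 and 487 CPM (1.53, 1.37 to 1.71), Prf1 27.6 and 44.8 CPM, the T-box factor Tbx21 17.3 and 62.3 CPM and the chemokine Xcl1 191 and 682 CPM, against Ccl5 at 6441 and 2653 CPM. Ifng was 365 and 406 CPM (1.11, 0.992 to 1.25), and its direction turns under that scaling. Prf1 turned in 7 of the settings that change which cells are kept or called T-like, Gzmb at a clustering resolution of 0.5 and Ly6c2 at a resolution of 2. The naive and memory genes Ccr7 (217 and 29.2 CPM) and Lef1 (111 and 42.8) were lower and Ly6c2 (429 and 826) higher. Cd274 was 39.9 and 77.9 CPM (1.95, 1.45 to 2.62). Other genes chosen by rule were Col3a1 (95 and 552 CPM), Irf8 (73.4 and 415), Il10 (39.2 and 5.84) and Cd8b1 (117 and 30.2).

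The share of YUMMER T-like cells with a CD8 transcript was 17.1% (15.1 to 19.2) and 13.4% (10.4 to 16.9), against 1.05% and 0.858% of NK-like cells, and its direction turned at a clustering resolution of 0.5 and where each cell was named by its highest mean marker. The share with Cd4 was 26.2% (23.9 to 28.7) and 15% (11.8 to 18.6), against 5.26% and 2.15% of NK-like cells. T-like cells had median depths of 1854 and 1843 UMIs and NK-like cells of 2481 and 2626 UMIs. The clusters behind the class differed: cluster 8, led by Nkg7 and Gzmk, held 44.3% of the control's T-like cells and 4.24% of those in sh3. Cluster 10, led by Gzma, held 32.5% and 50.7%, and cluster 7, led by Tnfrsf4, held 23.2% and 45.1%. All 15 measured matrix genes (median 1.96, 0.63 to 2.54) and all 13 mitochondrially encoded transcripts (median 0.63, 0.49 to 0.78) were higher in the sh3 T-like cells. Col6a2 was 12 and 83.7 CPM here and 193 and 748 CPM in vector-bearing cells.

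In YUMMER macrophage-like cells Retnla and Cxcl2 were higher in the sh3 library, and Ly6c2 and Plac8 lower. puroR was 81.6 and 5.03 CPM in this class, against 220 and 82.9 CPM in vector-bearing cells. More RNA of vector-bearing cells in the control class is therefore not excluded as part of the differences below. Retnla, a secreted product of alternatively activated macrophages, was 667 and 5284 CPM (7.93, 6.72 to 9.41), and 11 of 16 genes of that program were higher (median 1.03, -0.28 to 2.40). The inflammatory Cxcl2 was 354 and 1176 CPM (3.33, 2.64 to 4.25) and Il1b 408 and 816 CPM, and 10 of 13 inflammatory genes were higher (median 0.59, -0.51 to 1.17). MHC class II genes were higher for 7 of 9 members (median 0.57, -0.19 to 0.89), with H2-Aa at 3864 and 7137 CPM. Il1b turned lower at both other mitochondrial limits and H2-Aa at the limit of 25%. Ly6c2 was 644 and 50.3 CPM (12.8-fold lower, 8.96 to 18.7) and Plac8 730 and 81.7 CPM. Both are markers of the monocyte-like class, which held 267 and 34 cells. The trimmed-mean shift of this class was -0.20, opposite in sign to that of the T-like cells, so that scaling raises these log2 ratios. In YUMMER NK-like cells 16 of 18 cell cycle genes were higher (median 1.38, 0.58 to 1.87), Gzma was 44.8 and 174 CPM, and the granzyme Gzmf was 734 and 92.4 CPM (7.94-fold lower, 6.02 to 10.6).

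The NILER libraries address how blood cells inside treated tumours differ when Itch is targeted. Macrophage-like, monocyte-like and dendritic-like cells held higher shares of the shITCH library. Monocyte-like cells were 1.13% (0.911 to 1.39; 91 cells) and 7.40% (6.88 to 7.95; 688 cells), a ratio of 6.55 (5.26 to 8.24). Macrophage-like cells were 1.57% (1.31 to 1.86; 126 cells) and 6.52% (6.03 to 7.04; 606 cells), a ratio of 4.17 (3.43 to 5.09), and dendritic-like cells 2.66% and 6.20%, a ratio of 2.33 (1.99 to 2.74). Plasmacytoid dendritic-like cells, which secrete type I interferon, were 0.832% and 1.91% and neutrophil-like cells 0.596% and 1.46%. Macrophage-like and monocyte-like cells together were 2.70% and 13.9%.

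T-like cells were 34.7% (33.7 to 35.7; 2793 cells) and 38.9% (37.9 to 39.9; 3620 cells) of kept NILER cells, and NK-like cells 16.9% (1364 cells) and 19.9% (1850 cells). Unnamed barcodes, mostly with few UMIs (medians 353 and 563.5), were 40.2% of shCTR and 16.2% of shITCH. Among named cells alone the direction turned for both lymphocyte classes: T-like cells were 58.0% and 46.5%, and NK-like cells 28.3% and 23.7%. The myeloid shares were higher in shITCH on both bases, with macrophage-like cells at 2.62% and 7.78% and monocyte-like cells at 1.89% and 8.83% of named cells. Their size depends on the naming, since the monocyte-like log2 ratio of 2.71 fell to 0.65 where each cell was named by its highest mean marker.

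In NILER T-like cells effector, exhaustion and activation genes were lower in the shITCH library, and cell cycle and type I interferon genes were higher. Of 24 cytotoxic genes 20 were lower (median -0.61, -1.05 to -0.19). Ifng, the main activating cytokine of these cells, was 662 and 235 CPM (0.355, 0.343 to 0.366), the granzyme Gzmb 929 and 450 CPM (0.484, 0.472 to 0.496), Gzme 124 and 32.8 CPM and the pore protein Prf1 188 and 104 CPM. Of 19 exhaustion genes 17 were lower (median -0.47, -0.81 to -0.19), with Pdcd1 at 475 and 266 CPM (0.560, 0.542 to 0.579) and Havcr2 at 105 and 50.4 CPM. Of 16 T cell receptor and activation genes 13 were lower (median -0.59, -1.14 to -0.07), with Nr4a1 at 487 and 181 CPM and Egr1 at 285 and 94.9 CPM, while Il2 was higher at 0.672 and 4.44 CPM. MAPK output genes were lower for 13 of 16 members (median -0.48, -0.92 to -0.07), with Dusp6 at 26.0 and 15.5 CPM and Dusp4 at 66.9 and 36.3 CPM. Cd274 was 43.7 and 24.9 CPM (0.571, 0.510 to 0.638), while Cd8a was nearly level at 622 and 591 CPM, as was B2m at 2832 and 2886 CPM, whose direction turned when each library was clustered apart.

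All 24 measured cell cycle genes were higher in the shITCH T-like cells (median 0.49, 0.41 to 0.64), with Mcm5 at 66.3 and 127 CPM, Pclaf at 207 and 380 CPM and Mki67 at 148 and 194 CPM (1.32, 1.25 to 1.38). Of 28 type I interferon genes 25 were higher (median 0.56, 0.29 to 0.66), with Slfn5 at 18.3 and 34.7 CPM and Ifi44 at 1.90 and 5.09 CPM. The interferon gamma response did not shift, with 13 higher and 13 lower (median 0.02, -0.31 to 0.15): the adhesion gene Icam1 was 222 and 90.6 CPM. Of 20 hypoxia genes 18 were lower (median -0.38, -0.60 to -0.14), with Bnip3 at 13.9 and 7.03 CPM, and all 23 oxidative phosphorylation genes were higher (median 0.30). Genes induced by tissue dissociation were lower for 20 of 21 members (median -0.87, -1.36 to -0.71), and this list includes heat shock and immediate-early genes, Nr4a1 and Egr1 among them. All 13 mitochondrially encoded transcripts were higher (median 0.26, 0.17 to 0.44).

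The NILER genes chosen by rule in T-like cells were, on the lower side, the heat shock genes Hspa1a (406 and 33.4 CPM; 0.0824, 0.0762 to 0.0889) and Hspa1b (156 and 14.2), Spp1 (482 and 70.0), Klra3 (97.4 and 14), Ccnb1ip1 (67.7 and 10.0), the granzymes Gzmf (328 and 62.9) and Gzmd (117 and 23.3), and Chl1 (14.9 and 2.5). On the higher side they were Aif1 (4.2 and 26.7 CPM; 6.35, 4.99 to 8.19), Mpeg1 (1.29 and 9.30), Ccl8 (10.1 and 54.4), Fcgr4 (0.784 and 6.20), Rln3 (3.98 and 20.4), Clec4a3 (0.784 and 5.46), Igf1 (0.616 and 4.53) and Ccl7 (0.896 and 5.69). Aif1, Mpeg1, Fcgr4 and Clec4a3 are genes of macrophages, whose share was higher in the same library. All 9 complement and phagocytosis genes (median 1.79, 1.35 to 2.42) and all 10 MHC class II genes (median 1.13, 0.58 to 1.67) were higher in the T-like cells too, with C1qc at 8.96 and 36.8 CPM and H2-Aa at 22.9 and 83.8 CPM. Of 9235 genes with at least 100 summed UMIs, 151 were at least 2-fold higher and 149 at least 2-fold lower.

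**Figure D4:**
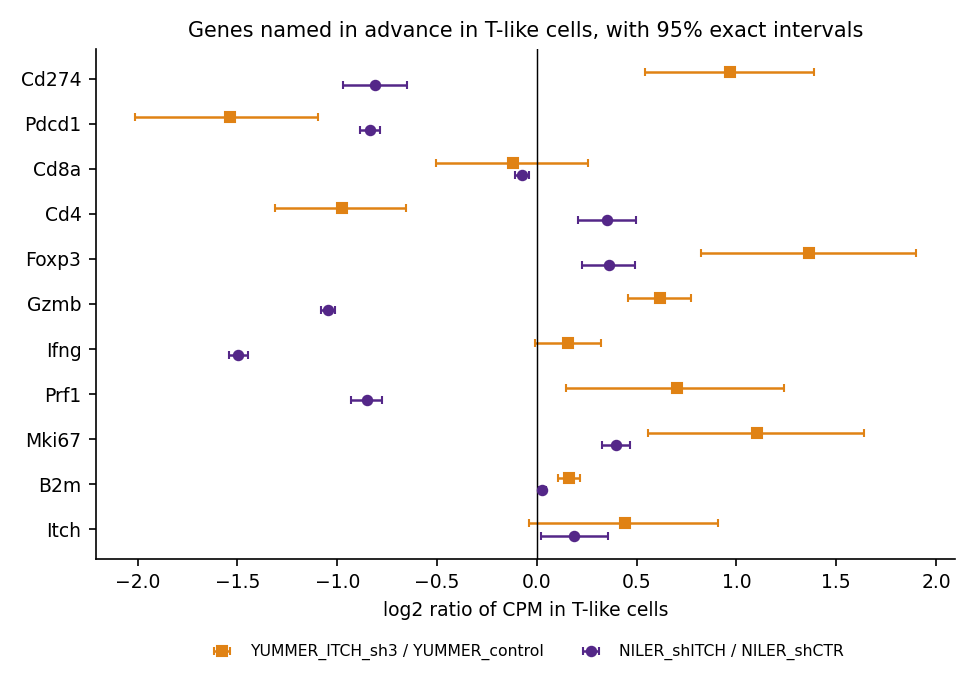
Log2 ratio of CPM (horizontal axis; hairpin library over control library) for 11 genes in YUMMER T-like cells (squares) and NILER T-like cells (circles), with bars for 95% exact intervals. Gzmb was 318 and 487 CPM in YUMMER and 929 and 450 CPM in NILER, and YUMMER Ifng and B2m fall below 0 under trimmed-mean scaling, whose shift is 0.21.

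NILER T-like cells with a CD8 transcript were 82.2% (80.8 to 83.6) and 76.9% (75.5 to 78.2), cells with Cd4 12.2% (11 to 13.4) and 15.2% (14 to 16.4), cells with Foxp3 9.31% (8.26 to 10.4) and 12.4% (11.3 to 13.5), and cells with Mki67 22.4% (20.8 to 24.0) and 30.5% (29.0 to 32.0). Median depth was 5320 and 4366.5 UMIs. Thinned to 1000 UMIs per cell the shares were 68.1% and 61.3% for CD8, 4.04% and 6.16% for Cd4, 3.54% and 4.98% for Foxp3, and 8.42% and 10.7% for Mki67. As background, 11.8% and 18.3% of B-like cells had a CD8 UMI, 0.440% and 0.486% of NK-like cells a Cd4 UMI, 0.733% and 0.378% of NK-like cells a Foxp3 UMI, and 3.92% and 5.63% of B-like cells an Mki67 UMI. Rates were higher in other classes. CD8 UMIs were found in 36.5% and 58.4% of macrophage-like cells, and Cd4 UMIs in 5.56% and 7.59%. Foxp3 UMIs were found in 2.20% and 4.07% of monocyte-like and 3.17% and 1.98% of macrophage-like cells. Mki67 UMIs were found in 12.6% and 14.4% of NK-like cells. Background therefore differs between classes and libraries. Cluster 8, led by Pdcd1 and Ifng, held 47.0% of the T-like cells in shCTR and 16.9% in shITCH, and cluster 4, led by Cxcr6 and Ccl5, held 2.11% and 20.9%.

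NILER NK-like cells shared the lower Ifng and the higher cell cycle genes of the T-like cells, while Gzmb and Prf1 were not lower. Ifng was 208 and 83.6 CPM (0.403, 0.371 to 0.438), Gzmb 582 and 610 CPM (1.05, 1.01 to 1.09) and Prf1 243 and 331 CPM (1.36, 1.29 to 1.44). Of 24 cytotoxic genes 13 were higher and 11 lower (median 0.04, -0.35 to 0.32). The clusters behind the class differed: cluster 11, with Rrm2 and Stmn1 among its leading genes, held 6.89% and 13.2% of NK-like cells, cluster 5.3 held 2.71% and 17.9%, and cluster 1 held 66.9% and 54.4%. Dissociation stress genes were lower for 20 of 21 members (median -1.07, -1.48 to -0.85), and all 13 mitochondrially encoded transcripts were higher (median 0.32, 0.16 to 0.41). All 24 cell cycle genes were higher (median 0.61, 0.47 to 0.78), and 20 of 26 type I interferon genes were lower (median -0.18, -0.29 to -0.05). That list and Gzmb turned when CPM was averaged over cells. The chemokine Ccl1 was 31.9 and 0.398 CPM (80.3-fold lower, 31.0 to 297), and Hspa1a 531 and 37.3 CPM. Ifitm1 was higher at 17.5 and 65.9 CPM (3.76, 3.13 to 4.53), and so were the myeloid genes Wfdc17 (1.34 and 10.0 CPM), Lyz2 (9.75 and 33.8) and Ccl8 (4.39 and 16.9).

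NILER macrophage-like cells held less of MHC class II and complement in the shITCH library. All 9 measured MHC class II genes (median -0.68, -1.05 to -0.17) and all 11 complement and phagocytosis genes (median -0.46, -0.93 to -0.18) were lower, with H2-Eb1 at 2409 and 1002 CPM and C1qa at 1898 and 994.5 CPM. Il1b was 261 and 63.3 CPM (4.12-fold lower, 3.29 to 5.14) and Cxcl2 241 and 84.4 CPM, both of which turned without doublet removal. Dissociation stress genes were lower for 20 of 21 members in this class (median -1.07, -1.28 to -0.82), and all 13 mitochondrially encoded transcripts were higher (median 0.21, 0.10 to 0.47). The complement list turned when each library was clustered apart. Of 28 type I interferon genes 25 were higher (median 0.34, 0.30 to 0.65). The lymphocyte genes Gimap7 (32.8 and 143 CPM) and Cxcr6 (95.1 and 300.3) were higher in this class as well. CD8 UMIs were found in 36.5% and 58.4% of its cells. More T cell RNA in the shITCH class is therefore not excluded as part of the lower MHC class II and complement values. In monocyte-like cells the T cell genes Cd3d (39.7 and 199 CPM) and Lat (11.7 and 70.6) were higher, except where each cell was named by its highest mean marker, S100a9 was 0 and 233 UMIs, at least 10.1-fold higher, and Cxcl10 was 542 and 233 CPM (2.32-fold lower, 2.00 to 2.70). S100a9 leads the neutrophil-like cluster, whose share was higher in shITCH, so RNA carried over from neutrophil-like cells is not excluded for it. In dendritic-like cells 25 of 28 type I interferon genes were higher (median 0.33, 0.27 to 0.58), 9 of 10 MHC class II genes were lower (median -0.25, -0.41 to -0.08), and Hspa1b was 135 and 15.5 CPM. Dissociation stress genes were lower for 19 of 21 members in dendritic-like (median -0.44, -0.62 to -0.20) and in monocyte-like cells (median -0.43, -0.83 to -0.15). The dendritic type I interferon list turned at a clustering resolution of 0.5, and the MHC class II list when each library was clustered apart.

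Of 11 measures of the T-like cells, 7 lay on the same side in both models by sign alone. The share with Foxp3 (log2 ratios 1.5 in YUMMER and 0.41 in NILER) and the type I interferon (0.45 and 0.56) and cell cycle lists (0.17 and 0.49) were higher in the hairpin libraries. The share with Mki67 was higher in NILER (0.45). In YUMMER (0.20) it was 2.92% and 3.35% (ratio 1.15, 0.587 to 2.13), near the 1.83% and 3.49% of macrophage-like cells. The interferon gamma list was higher in YUMMER (0.50) and near level in NILER (0.02, -0.31 to 0.15). The share with CD8 (-0.35 and -0.10) and the exhaustion list (-0.31 and -0.47) were lower. In YUMMER neither side is settled by its interval. The CD8 ratio was 0.784 (0.580 to 1.05), and the interval of the exhaustion median given above spans 0. The share with Cd4 (-0.81 and 0.32) and the cytotoxic (0.29 and -0.61), T cell receptor (0.25 and -0.59) and MAPK output lists (0.07 and -0.48) lay on opposite sides. The YUMMER cell cycle and MAPK medians lie under the 0.21 by which trimmed-mean scaling shifts that class, so both turn negative there. The YUMMER T cell receptor median of 0.25 lies only just above that shift. Over 10 settings between 6 and 9 measures were on the same side, and no difference between the models was tested.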

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

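The tests on the mitochondrial filter, with or without clusters, on T-like cells among named immune cells and on other backgrounds for the unnamed barcodes were chosen after the result was seen; the other tests below were fixed before. The differences between the models were not tested, and the models differ in line, hairpin, day, sort and the first bases of their cell barcodes.

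Monocyte-like, dendritic-like and T-like shares, and T-like and NK-like cells combined, lay on opposite sides of 1 in the 2 models, each beyond its own counting interval. Macrophage-like and NK-like shares lay on the same side in the main setting. The NK-like side is not firm. In NILER it turned among named cells, with at least 500 genes per cell and where each cell was named by its highest mean marker. In YUMMER it turned at a clustering resolution of 0.5. For monocyte-like cells the log2 share ratio was -2.82 in YUMMER and 2.71 in NILER, a gap of 5.54. For dendritic-like cells it was -0.94 and 1.22 (gap 2.16), for T-like cells -1.43 and 0.17 (gap 1.59), and for T-like and NK-like cells combined -0.92 and 0.19 (gap 1.11). The share of T-like cells with Cd4 was -0.81 and 0.32 (gap 1.13). Within T-like cells the T cell receptor and activation genes, such as Nr4a1 and Egr1, had a median of 0.25 in YUMMER and -0.59 in NILER (gap -0.84), and both genes are in the dissociation stress list too. The hypoxia and glycolysis genes had medians of 0.45 and -0.38 (gap -0.83). The YUMMER intervals were 0.07 to 1.12 for the T cell receptor list and 0.14 to 0.77 for the hypoxia list. Both lower bounds lie below the 0.21 by which trimmed-mean scaling shifts YUMMER T-like cells. Under that scaling both medians stay above 0, but neither YUMMER side is settled by its interval. The NILER directions for T-like cells, and for T-like and NK-like cells combined, turned among named cells. Both also turned with at least 500 genes per cell and where each cell was named by its highest mean marker.

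Unnamed NILER barcodes, which enter no comparison of classes, held puroR. It was 20.03 CPM (46 UMIs) in shITCH and 1.45 CPM (7 UMIs) in shCTR, a ratio of 13.8 (6.18 to 36.2), although both libraries were sorted for CD45. Over both libraries it was highest in unnamed cluster 17.1, led by Ifit1 and Rsad2, at 100 CPM (120 cells, median 3077.5 UMIs). Cluster 3 held 16.4 CPM and the largest unnamed cluster, 7, held 1.91 CPM. In macrophage-like cells puroR went the other way, at 14.8 CPM (9 UMIs) in shCTR and 1.88 CPM (5 UMIs) in shITCH, a ratio of 0.128 (0.0336 to 0.424).

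The lower T-like and B-like shares of the YUMMER sh3 library were set against loss to the mitochondrial filter and a larger tumour fraction. Keeping cells of up to 25% mitochondrial UMIs gave a log2 share ratio of T-like cells of -2.10 (-2.30 to -1.91), but the classes were redrawn, with 1184 and 260 T-like cells against 1335 and 448, so this decides nothing. Over all cells of at least 200 genes, with no mitochondrial limit and no clusters, the share with at least 2 T cell marker UMIs was 19.2% and 6.72% (log2 ratio -1.52, -1.66 to -1.38) and with at least 2 B cell marker UMIs 5.19% and 0.22% (-4.56, -5.33 to -3.88), which argues against the filter. Among named immune cells T-like cells were at -0.76 (-0.91 to -0.60), against a larger tumour fraction as the whole cause, although T-like and NK-like cells combined came only to -0.25. Targeting of Itch, the sampled animal and the dissected piece may each contribute and cannot be separated with 1 library per group.

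The lower Itch of the vector-bearing cells was set against the mix of clusters and against the spread of other genes. Pooled within 10 clusters, all of them lower, the log2 ratio was -0.54 (-0.66 to -0.41), which argues against the mix of clusters. Among 1369 genes of like abundance, however, the Itch ratio lay at percentile 3.94 (2.98 to 5.12), inside the central 95% that runs from -0.67 to 0.68. A difference of this size is therefore within what these 2 libraries show for genes no one targeted. The spread of those genes may also hold responses to the hairpin and the differing mix of clusters, so it does not measure variation between libraries alone. The percentile cannot decide between a knockdown and ordinary variation between libraries, and both remain open. The hairpin is the biological explanation that the design names.

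The higher monocyte-like and macrophage-like shares of the NILER shITCH library were set against myeloid cells hidden among the unnamed barcodes and against mixing with T cells. Cells of these classes without a T cell UMI (93 and 527 cells) had a log2 share ratio of 2.30 (1.97 to 2.63), which argues against doublets and free T cell RNA. Adding the myeloid cells estimated among unnamed barcodes, from their marker rate above that of T-like cells, gave 2.06 (1.90 to 2.22), and with the lowest rate of any class of at least 50 cells as background it gave 1.17 (1.04 to 1.29), which argues against hidden cells of the named kind as the whole cause. With no background taken off it was 0.65 (0.54 to 0.75). Hidden myeloid cells that carry fewer markers than named ones, and a difference tied to the hairpin, may both contribute.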

How the results depend on the processing

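Settings that use named cells or named immune cells as the base, leave out cycling clusters, or use only T-like cells with a CD8 UMI were chosen after seeing the data; all others were fixed before. No paired analysis was possible because each group holds 1 library and the replicate number 1 is all that libraries share. Values are log2 ratios unless called counts, and the cause of each difference was not tested.

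Of 246 values of the 20 main YUMMER measures 195 stayed within the main interval (counts within 1.5 times), 50 moved and 1 reversed. A change of sign counts as reversed only where the main interval excludes 0. The YUMMER share with CD8, whose main value of -0.35 (-0.79 to 0.07) does not, changed sign in 2 settings given below. Of 264 values of the 21 main NILER measures 212 stayed, 43 moved and 9 reversed. Other named measures gave 328 of 373 (YUMMER) and 263 of 363 (NILER) within the interval, with 4 reversed in each. Itch in vector-bearing cells lay between -0.76 and -0.52, the YUMMER T-like share between -2.21 and -0.76, the B-like share between -8.50 and -6.23, and the share of T-like cells with Foxp3 between 1.48 and 2.61. The B-like range leaves out the count of B cell marker UMIs without clusters, which gave -4.56. In NILER T-like cells the cytotoxic median lay between -0.67 and -0.54, the exhaustion median between -0.69 and -0.42 and the cell cycle median between 0.40 and 0.86. Named genes whose main interval excludes 1 kept their side in 8835 of 9072 (YUMMER, 97.4%) and 9560 of 9780 (NILER, 97.8%) comparisons. They were chosen largely for the size of their ratios in the same counts, so these rates are not independent support for them.

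With at most 5% mitochondrial UMIs, YUMMER values were -0.76 for Itch in vector-bearing cells, -1.24 for T-like, 2.10 for NK-like, 1.77 for macrophage-like, -2.30 for monocyte-like, 0.24 for vector-bearing and -0.42 for T-like and NK-like cells combined. Dusp6 in vector-bearing cells reversed to -0.071, and NILER NK-like cells were at 0.081. With at most 25%, YUMMER T-like cells were at -2.10, NK-like cells at 0.89, the shares with CD8 and Cd4 at -0.99 and -0.22, and the NILER type I interferon median at 0.66.

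With at least 500 genes per cell, YUMMER T-like cells were at -1.72, macrophage-like at 3.11, monocyte-like at -1.90 and the last 2 combined at 0.068. In NILER T-like (-0.083), NK-like (-0.088) and both combined (-0.085) reversed, dendritic-like cells were at 0.96, macrophage-like and monocyte-like combined at 1.95 and the type I interferon median at 0.67.

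At resolution 0.5 YUMMER NK-like cells reversed to -0.061, with T-like cells at -1.87, macrophage-like at 0.41 and the shares with CD8 and Cd4 at 0.088 and -0.30. NILER monocyte-like cells were at 2.04, with macrophage-like cells added at 1.95, and the type I interferon median at 0.69. At resolution 2 YUMMER T-like cells were at -2.18, NK-like at 0.89, macrophage-like at 2.98 and the shares with CD8 and Cd4 at -1.09 and -0.073; NILER T-like cells were at 0.33, T-like and NK-like combined at 0.31 and the cell cycle median at 0.40. With 4000 variable genes YUMMER T-like cells were at -2.21, NK-like at 0.76, monocyte-like at -2.05 and the shares with CD8, Cd4 and Foxp3 at -1.27, -0.075 and 2.28. NILER NK-like cells were at 0.12, T-like and NK-like combined at 0.12 and the type I interferon median at 0.67.

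With each library clustered apart, YUMMER NK-like cells were at 0.43, macrophage-like at 4.43 and macrophage-like and monocyte-like combined at 0.93. NILER T-like cells were at 0.33, NK-like at 0.55, both combined at 0.41, macrophage-like at 1.00, dendritic-like at 2.07, macrophage-like and monocyte-like combined at 1.63, the share with Mki67 at 0.65 and the cell cycle median at 0.86. A count of 263 genes was 2-fold higher in NILER T-like cells, and B2m there reversed to -0.0087.

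With each cell named by its highest mean marker, YUMMER T-like cells were at -1.99, monocyte-like at -0.98, T-like and NK-like combined at -1.34 and the share with CD8 at 0.10. In NILER T-like (-0.034), NK-like (-0.28) and both combined (-0.11) reversed. Macrophage-like cells were at 0.78, monocyte-like at 0.65, both combined at 0.68, dendritic-like at 0.78 and the shares with CD8 and Cd4 at -0.0022 and 0.55.

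With the mean CPM over cells, Mki67 in YUMMER vector-bearing cells (-0.039) and Xist in NILER T-like cells (-0.024) reversed, and Itch over NILER cells was at 0.072. Thinned to 1000 UMIs, the YUMMER share with Foxp3 was at 2.61 and the NILER share with Cd4 at 0.61, Mki67 (-0.029) and Xist (-0.15) in the same classes reversed, and counts of 2-fold higher and lower genes were 60 and 49 in YUMMER vector-bearing and 54 and 89 in NILER T-like cells. With at least 20 summed UMIs these counts were 386 and 416, and 405 and 278; with at least 400 they were 82 and 91, and 53 and 92, as more or fewer genes enter. Without doublet removal NILER NK-like cells were at 0.10 and macrophage-like at 2.36.

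Among named immune cells YUMMER T-like cells were at -0.76, NK-like at 2.11, macrophage-like at 2.89, monocyte-like at -2.15, T-like and NK-like combined at -0.25 and macrophage-like and monocyte-like combined at 1.21. Among named cells NILER T-like (-0.32), NK-like (-0.25) and both combined (-0.30) reversed, with macrophage-like at 1.57, monocyte-like at 2.23, both combined at 1.88 and dendritic-like at 0.74. Without cycling clusters Mki67 in YUMMER vector-bearing cells reversed to -0.087, and among NILER T-like cells with a CD8 UMI B2m reversed to -0.0013.

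No value came from YUMMER monocyte-like cells at resolution 0.5, from vector-bearing cells when each cell was named by markers, from YUMMER B-like cells when libraries were clustered apart, from YUMMER neutrophil-like cells with at least 500 genes, or from NILER monocyte-like cells with at least 500 genes, without doublet removal or clustered apart. Pericyte-like cells gave none with at most 5% mitochondrial UMIs or clustered apart. Depth limits genes under 100 summed UMIs and classes of few cells: in YUMMER macrophage-like cells Itch rested on 6 and 28 UMIs, with an interval from 0.525 to 3.82.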

Other observations

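The classes, lists and genes below were in the plan except Mid1, Ddx3y and the genes read across all classes, which were chosen after their values were seen. In YUMMER fibroblast-like cells the matrix protease Mmp13 was 18.9 and 306 CPM in control and sh3 (ratio 16.2, 8.90 to 32.8), the growth factor Ptn 62.0 and 383 CPM, Ltc4s 36.2 and 177 CPM (lower where each cell was named by its highest mean marker) and the matrix protein Postn 2073 and 4541 CPM. Lower were Car3 at 155 and 0 UMIs, at least 80.8-fold lower, Slpi 191 and 1.1 CPM (174-fold lower, 30.5 to 6915), Myoc 410 and 9.91 CPM and Cxcl14 787 and 29.7 CPM. Of 22 matrix genes 12 were higher and 10 lower. In endothelial-like cells the collagen Col6a1 was 9.85 and 131 CPM (13.3, 7.46 to 25.7) and the metallothioneins Mt1 and Mt2, which bind metals, were 82.6 and 688 CPM and 35.6 and 308 CPM. The fatty acid carrier Fabp4 was 667 and 15.5 CPM (43.2-fold lower, 25.1 to 81.4) and its partner in fat uptake Cd36 228 and 40.4 CPM. All 6 measured MHC class II genes were lower there (median -2.03, -3.18 to -1.49), with H2-Eb1 at 139 and 22.6 CPM and Cd74 at 851 and 93.9 CPM. Cd74 was lower in mast or basophil-like (372 and 48.6 CPM) and NK-like cells (520 and 223 CPM) as well, in the library with fewer B-like cells, so RNA carried over from other cells is not excluded.

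In YUMMER dendritic-like cells 21 of 22 type I interferon genes were higher in the sh3 library (median 0.74, 0.31 to 1.26), above the 0.14 by which trimmed-mean scaling shifts this class. The RNase gene Ear2 was 71.5 and 373 CPM (5.22, 3.79 to 7.26) and Wdfy4, which cross-presentation needs, 78.3 and 242 CPM. Ly6d was 107 and 0 UMIs, at least 11.4-fold lower, a direction that turned under the same naming, and Apol7c, a gene of cross-presenting dendritic cells, 439 and 53.3 CPM. Ly6d is also a leading gene of the B-like cluster, which held 379 and 2 cells, so RNA carried over from B-like cells is not excluded for it. In macrophage-like cells Rnase2a was 0 and 111 UMIs, at least 10.3-fold higher, and Mmp12 59.0 and 341 CPM. In mast or basophil-like cells the protease Mcpt2 was 1018 and 4254 CPM (4.18, 3.67 to 4.76) and the chemokine Ccl5 797 and 97.2 CPM. Ccl5 was lower in T-like cells too, and their share was lower, so RNA carried over from them is not excluded for it.

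Mid1, an X-linked E3 ubiquitin ligase gene (chromosome X, 169685199 to 170005736, plus strand), was the 1 gene of 2565 at least 2-fold higher in the sh3 library in all 7 YUMMER host classes compared. It was 4.98 and 195 CPM in T-like cells, 4.53 and 256 CPM in macrophage-like, 5.67 and 217 CPM in dendritic-like, 12.1 and 122 CPM in endothelial-like and 8.61 and 101 CPM in fibroblast-like cells, 3 and 62 UMIs in NK-like and 0 and 51 UMIs in mast or basophil-like cells. Vector-bearing cells showed little of it, at 8.85 and 11.3 CPM (1.28, 1.14 to 1.44), and NILER T-like cells held 9.63 and 15.4 CPM. Xist was 679 and 1410 CPM in YUMMER T-like cells and 698 and 711 CPM in macrophage-like cells, and 413 and 472 CPM in NILER T-like cells, where thinning cells turned its direction to a log2 ratio of -0.15. The Y-linked Ddx3y had 0 and 19 UMIs in vector-bearing cells, and 0 UMIs in both libraries in each of the 7 host classes. No explanation was tested. The hosts of the libraries may differ in substrain, which would bear on every YUMMER comparison of host cells.

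Hspa1a, an inducible heat shock gene (chromosome 17, 34969190 to 34972156, minus strand), was the 1 gene of 1505 at least 2-fold lower in the shITCH library in all 8 NILER classes compared. It was 406 and 33.4 CPM in T-like, 531 and 37.3 CPM in NK-like, 502 and 11.6 CPM in B-like, 474 and 71.9 CPM in dendritic-like, 436 and 79.1 CPM in macrophage-like, 658 and 138 CPM in monocyte-like and 688 and 26.1 CPM in mast or basophil-like cells, and 42.2 and 20.3 CPM in plasmacytoid dendritic-like cells. Unnamed barcodes held 403 and 94.9 CPM. In YUMMER T-like cells Hspa1a was 5306 and 4356 CPM. No explanation was tested.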
